A study of Picea schrenkiana with 12 samples.

How the data were processed

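Poly(A) RNA from young roots of Picea schrenkiana (Tianshan or Schrenk's spruce, a conifer of Central Asian mountains) was sequenced as 12 libraries in 4 groups of 3. Per the labels' protocols, seedlings were raised for 2 weeks at 23 °C by day and 18 °C by night under 6000 lux and were then irrigated for 10 days with water or with 1 mM 3,4-dihydroxyacetophenone (DHAP), a phenolic compound. The DHAP seedlings were sorted by how they had grown into tall seedlings (labelled high), short seedlings (dwarf) and seedlings whose growth had stopped (suppressed), and the roots were cut for RNA. The growth class is thus an outcome seen under the treatment and was not assigned at random, so a difference between a DHAP group and water holds the treatment and the class together. Per the labels' protocols, RNA integrity numbers were above 7 and a stranded Illumina kit was used. Per the submitters' processing notes, cutadapt was used, with no version given. The assembler, the read counter and the reference they used are not given in the sources used here.

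One table of 26911 genes in 12 value columns was analysed, and each column name matched the label of 1 sample. The contig names have the form that the Trinity assembler gives, and each row carries a length (median 837 bases, from 201 to 14370) and best-hit annotation from public protein databases. The deposited values were taken to be TPM, a measure of transcripts scaled by contig length and by the library total: no label or header names the unit, and this was inferred from the values, because the columns summed to between 949771 and 963254 and low values of short contigs rose in steps that depended on length. The smallest of the rows' largest values was 6.01 TPM, so that the table holds no rows of low values throughout. The total number of reads behind each library is unknown. For a contig of 201 bases, the steps gave the value of 1 read as 1.01 TPM in high replicates 1 and 3 and as much as 1.66 TPM in suppressed replicate 2. Within 0.1 of a read, 97.0% to 99.0% of the low values in each library were whole reads, where 20.0% would be by chance. Values of a few TPM on short contigs therefore rest on a few reads.

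Gene names are those of the best protein hit of each contig, in whatever species that hit was found. Of the 26911 genes, 12879 had a Swiss-Prot description and 13502 had an informative description. By the taxon named in the annotation, 9597 contigs matched conifers best, 632 matched fungi and 1110 matched animals, and 15572 matched other taxa or had no match. Fungal and animal matches were read from the Swiss-Prot hit alone, unless the other database hit was a conifer. Plant contigs whose nearest Swiss-Prot entry is fungal or animal can therefore be among them. No genome position is given because no genome was used here. Close paralogs can share reads or be split over several contigs, so the values of single members of the peroxidase, esterase, chitinase and terpene synthase families are uncertain to that extent.

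Values were analysed as log2(TPM + 1), so that fold changes of genes with low values are understated. The 26897 genes with at least 1 TPM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 (trend fitted to the mean level), in a single fit of 4 group means over the 12 libraries with 8 residual degrees of freedom. The 6 pairwise comparisons and the mean of the 3 DHAP groups against water were contrasts of that fit. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called changed at an adjusted p under 0.05. In simulated data with the real levels and spreads and 200 genes changed, the test recovered 65.7% of genes changed 1.5-fold, 73.1% at 2-fold and 87.9% at 4-fold in a simulated comparison of high with water over 25331 genes, and it called 13 genes that had not been changed. The changed genes were drawn from those at about 5 TPM or more in water. Far fewer genes were changed than the real comparisons called, so these rates do not describe low values or the real fits. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

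In all, 34 lists of genes were set by word patterns in the descriptions. They covered phenylpropanoid, flavonoid and terpenoid enzymes, class III peroxidases, glutathione S-transferases, glycosyltransferases, cytochrome P450 enzymes, ABC and MATE transporters, antioxidant enzymes, and the auxin, abscisic acid, ethylene, jasmonate, gibberellin, cytokinin and brassinosteroid pathways. Others were wall loosening, cellulose and structural wall proteins, cell division, histones, cytosolic ribosomal proteins, pathogenesis-related and heat shock proteins, WRKY, MYB and NAC factors, aquaporins, mineral transporters, and sucrose and starch metabolism. Lists for photosynthesis (green shoot tissue), late embryogenesis and seed storage proteins (seed), casparian strip and suberin (endodermis), xylem differentiation (xylem) and root hair genes (epidermis) served as markers of tissues. Each list was tested with camera from limma at a preset correlation of 0.01, adjusted over the 204 tests of 34 lists in 6 comparisons, and again with an estimated correlation. Members that rose or fell are counted at the adjustment over all genes and also as adjusted over the list alone.

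The genes named are, for each pairwise comparison, the 8 that rose most and the 8 that fell most among called genes whose 2 groups did not overlap (which chance gives for 10% of genes in a comparison of 3 with 3), with a mean of at least 5 TPM in the higher group and an informative description. In addition, the 2 members with the smallest p-value of each list were eligible, if their mean was at least 5 TPM in either group. The groups, the tests, the lists, this rule and the alternatives listed next were chosen before the data were examined. The alternatives were a fit with the replicate number as a block, limma without a trend, median-of-ratios scaling of the libraries, no filter, a filter of 5 TPM, a pseudocount of 0.1, a 2-fold minimum, a fit of only the libraries compared, leaving out each library in turn, and, for lists, fry in place of camera and the estimated correlation. Counts and lists restricted by the taxon of the best hit, and lists after rescaling, were added after seeing the data.

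Libraries of a group correlated over genes with Pearson's r from 0.933 to 0.953 on the log scale. Read counts implied by the steps differed within groups by a chi-square per degree of freedom between 1.64 and 2.78, above the value of 1 for counting noise alone, so no libraries were treated as copies of each other. The median coefficient of variation of genes at 100 TPM or more was 2.12% to 3.18% within groups. The labels call the 3 libraries of a group biological replicates but do not say whether they came from separate seedlings or pools, and the submitters' design text speaks of 4 constructed libraries. The p-values therefore measure only the spread between these samples, which may be technical, and the text gives weight to the size of each change.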

Results

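Expression was measured by poly(A) RNA sequencing in young spruce roots of 4 groups with 3 libraries each: seedlings given water, and seedlings given 1 mM DHAP that had grown tall, had stayed short or had stopped growing. Between 23499 and 24989 of the 26911 contigs reached 1 TPM in a library. The number of reads per library was not available, and for the shortest contigs 1 read was worth between 1.01 and 1.66 TPM. Levels below are means ± SD in TPM (n = 3), fold changes are log2 values on the log2(TPM + 1) scale from limma, and adjusted p-values of lists are from camera in limma. For each gene named for the size of its change, all 3 libraries of 1 group lay above all 3 of the other.

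On the first principal component, which held 45.6% of the variance, the suppressed roots lay farthest from the water and high roots and the dwarf roots lay between. The second component, with 18.5%, parted the water and suppressed roots from the high and dwarf roots. Across genes, which are not independent replicates, Pearson's r between a water library and a high library was 0.879 to 0.905, against 0.812 to 0.850 for dwarf and 0.778 to 0.810 for suppressed libraries.

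**Figure D1:**
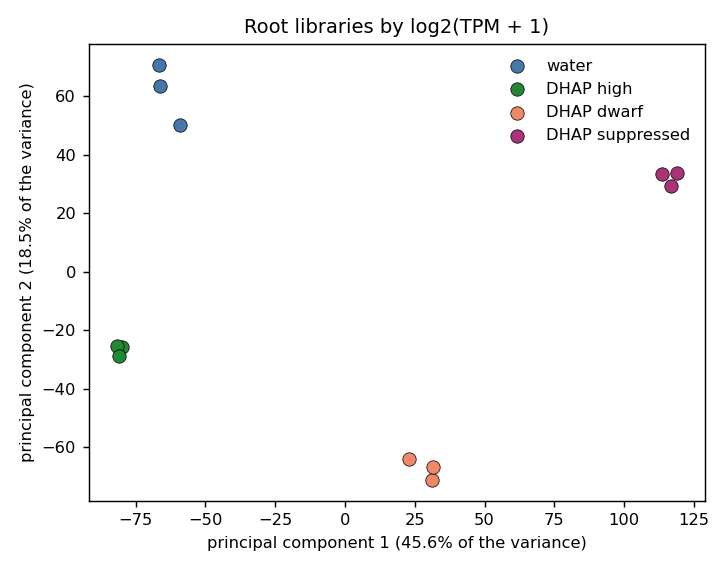
Each point is 1 of the 12 root libraries, placed by the first and second principal components of log2(TPM + 1), with 45.6% and 18.5% of the variance. The 3 libraries of each group lie together, and the water and high groups lie at the left, the suppressed group at the right.

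The first comparison asked how roots of seedlings that grew tall under DHAP differed from roots given water. Genes of photosynthesis, whose transcripts mark green tissue, were lower in the high roots: 0 of 50 members rose, 28 fell and 22 did not pass (0 and 32 adjusted over the list alone, median log2 change -0.80) (adjusted p = 8.38e-25, and 0.00833 with an estimated correlation). The small chain of ribulose bisphosphate carboxylase (TRINITY_DN17596_c0_g1), the enzyme that fixes carbon dioxide, fell from 108 ± 3.8 to 18.9 ± 1.10 TPM (log2 change -2.45). A chlorophyll a-b binding protein (TRINITY_DN19345_c0_g2) fell from 329 ± 8.41 to 107 ± 1.58 TPM (log2 change -1.61). A mannose-binding lectin (TRINITY_DN12880_c0_g1), a sugar-binding protein, rose from 0.14 ± 0.12 to 95.9 ± 4.25 TPM (log2 change 6.42), the largest rise among the genes named in this comparison. A flavonol synthase/flavanone 3-hydroxylase (TRINITY_DN21702_c0_g2), an oxygenase of the flavonoid pathway, fell from 72.5 ± 4.06 to 5.14 ± 0.50 TPM (log2 change -3.58).

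More class III peroxidases and structural wall proteins fell than rose in the high roots, while phenylpropanoid and lignin enzymes were not called (28 of 108 rose and 26 fell, 31 and 30 adjusted over the list alone, median -0.01 and mean 0.02, adjusted p = 0.668). Among class III peroxidases, secreted enzymes that act in lignification and in wall stiffening, 16 of 96 members rose, 36 fell and 44 did not pass (18 and 40 adjusted over the list alone, median log2 change -0.16) (adjusted p = 3.12e-06, and 0.0198 with an estimated correlation). Peroxidase 5 (TRINITY_DN24573_c0_g1) fell from 210 ± 11.9 to 67.0 ± 2.19 TPM (log2 change -1.63). Peroxidase 12 (TRINITY_DN21860_c0_g4) fell from 720 ± 13.5 to 359 ± 4.63 TPM. Of cellulose synthases and structural wall proteins, 1 of 46 members rose, 15 fell and 30 did not pass (1 and 16 adjusted over the list alone, median log2 change -0.13) (adjusted p = 3.16e-06, and 0.0243 with an estimated correlation). For xylem differentiation, 0 of 11 rose and 5 fell (1 and 7 adjusted over the list alone, median log2 change -0.25) (adjusted p = 9.27e-04, and 0.0247 with an estimated correlation). For the gibberellin list 1 of 16 rose and 7 fell (1 and 7 adjusted over the list alone, median log2 change -0.20) (adjusted p = 0.003, and 0.0328 with an estimated correlation). The gibberellin list holds mostly small cysteine-rich proteins named for their response to the hormone, such as Gibberellin-regulated protein 11 (TRINITY_DN15955_c0_g1) (log2 change -0.82, 24.3 ± 1.41 against 43.6 ± 1.57 TPM). The receptor GID1C (TRINITY_DN15740_c0_g1) rose from 16.8 ± 1.08 to 27.6 ± 1.12 TPM (log2 change 0.69). Wall loosening genes were also called lower, with 31 rising and 43 falling of 143 (31 and 48 adjusted over the list alone), but the call did not hold (adjusted p = 0.124 with an estimated correlation). Xyloglucan endotransglucosylase/hydrolase protein 31 (TRINITY_DN16380_c1_g3), an enzyme that cuts and rejoins a wall polymer, fell from 24.1 ± 0.56 to 7.87 ± 0.16 TPM (log2 change -1.50). Expansin-A1 (TRINITY_DN18450_c0_g2), which loosens walls, fell from 34.7 ± 0.84 to 15.7 ± 1.41 TPM (log2 change -1.10).

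Among pathogenesis-related proteins 19 of 128 rose and 37 fell (23 and 45 adjusted over the list alone, median log2 change -0.03). Among heat shock proteins 13 of 136 rose and 33 fell (13 and 35 adjusted over the list alone, median log2 change -0.06). Both lists were called lower, and neither call held (adjusted p = 0.0631 with an estimated correlation for the first, and adjusted p = 0.0716 with an estimated correlation for the second). Pathogenesis-related protein 5 (TRINITY_DN19289_c0_g3) fell from 361 ± 16.0 to 152 ± 4.10 TPM (log2 change -1.24). ABC and MATE transporters, which move small molecules across membranes, were called higher, with 22 rising and 3 falling of 132 (22 and 3 adjusted over the list alone, adjusted p = 0.288 with an estimated correlation). ABC transporter G family member 35 (TRINITY_DN17641_c0_g1) rose from 8.96 ± 0.44 to 16.1 ± 1.57 TPM (log2 change 0.77). Antioxidant enzymes were called lower with 10 rising and 19 falling of 99 (10 and 20 adjusted over the list alone, adjusted p = 0.201 with an estimated correlation). A GDSL esterase/lipase (TRINITY_DN21570_c0_g1) rose from 0.44 ± 0.38 to 33.6 ± 1.38 TPM (log2 change 4.62). A UPF0098 family protein (TRINITY_DN18327_c0_g2) rose from 1.19 ± 0.17 to 47.2 ± 0.73 TPM (log2 change 4.46). Hydrophobic protein LTI6B (TRINITY_DN20568_c0_g3), of a family of small membrane proteins induced by cold and salt, rose from 0.60 ± 0.13 to 17.5 ± 1.89 TPM (log2 change 3.53).

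In total, limma called 5483 of 26897 genes between high and water roots, 2984 higher and 2499 lower, and 1140 of the higher and 817 of the lower differed at least 2-fold. After median-of-ratios scaling the majority turned, with 2649 higher and 3107 lower. Most changes of 2-fold or more lay outside the contigs that matched conifers best, of which 140 were higher and 157 lower among 9596. Of 631 contigs with a fungal best hit, 243 were 2-fold higher and 70 lower, and of 1108 with an animal best hit, 17 were 2-fold higher and 238 lower. Cytosolic ribosomal proteins were called lower, with 65 rising and 133 falling of 519 (70 and 152 adjusted over the list alone, adjusted p = 0.223 with an estimated correlation), and histones higher, with 18 rising and 2 falling of 82 (18 and 2 adjusted over the list alone, adjusted p = 0.183 with an estimated correlation). Without contigs of fungal or animal best hit, 12 ribosomal proteins rose and 17 fell. Several of the genes named by size were of these kinds, such as a fungal-like trypsin (TRINITY_DN16899_c0_g1) (log2 change 3.75, 13.2 ± 0.83 against 0.05 ± 0.05 TPM). Major sperm protein 2 (TRINITY_DN16641_c0_g1), an animal-like contig named for a protein of nematode sperm, was at 53.6 ± 14.3 TPM in water and listed at 0 in all 3 high libraries.

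The next comparison asked how roots of seedlings that stayed short under DHAP differed from roots given water. Here more genes of the wall, xylem, cell division and aquaporin lists rose than fell. Of cellulose synthases and structural wall proteins, 36 of 46 members rose, 1 fell and 9 did not pass (37 and 2 adjusted over the list alone, median log2 change 0.98) (adjusted p = 7.75e-12, and 0.00833 with an estimated correlation). Fasciclin-like arabinogalactan protein 17 (TRINITY_DN15496_c0_g1), a cell-surface glycoprotein also on the xylem list, rose from 27.3 ± 1.19 to 104 ± 2.80 TPM (log2 change 1.90). Glucomannan 4-beta-mannosyltransferase 9 (TRINITY_DN16460_c0_g1), which makes the backbone of a hemicellulose, rose from 7.65 ± 0.57 to 34.6 ± 0.72 TPM (log2 change 2.04). For wall loosening, 94 of 143 members rose, 27 fell and 22 did not pass (95 and 29 adjusted over the list alone, median log2 change 0.73) (adjusted p = 8.60e-06, and 0.023 with an estimated correlation), with Xyloglucan endotransglucosylase/hydrolase 2 (TRINITY_DN23869_c0_g1) rising from 10.6 ± 0.95 to 123 ± 1.43 TPM (log2 change 3.43). All 11 genes of the xylem list, which are fasciclin-like arabinogalactan proteins and Protein IRREGULAR XYLEM 15, rose with a median log2 change of 1.55 (adjusted p = 4.87e-07, and 0.00833 with an estimated correlation). The fasciclin-like members are also on the cellulose and structural wall list, so the xylem and wall results are not separate evidence.

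Cell division genes rose in the dwarf roots: 57 of 88 members rose, 7 fell and 24 did not pass (57 and 7 adjusted over the list alone, median log2 change 0.63) (adjusted p = 3.17e-07, and 0.0411 with an estimated correlation). Cyclin-dependent kinase B1-1 (TRINITY_DN22544_c0_g1), a kinase of plant cells entering mitosis, rose from 28.8 ± 1.46 to 84.3 ± 1.57 TPM (log2 change 1.52). The regulatory subunit 2 of cyclin-dependent kinases (TRINITY_DN17228_c0_g2) rose from 44.0 ± 1.10 to 109 ± 1.58 TPM (log2 change 1.29). Of aquaporins, which are water channels, 16 of 19 rose and 2 fell (16 and 2 adjusted over the list alone, median log2 change 0.92) (adjusted p = 1.10e-06, and 0.0212 with an estimated correlation). The plasma membrane aquaporin PIP2-8 (TRINITY_DN23985_c0_g1) rose from 788 ± 10.2 to 1423 ± 16.0 TPM (log2 change 0.85). In the casparian strip and suberin list, the marker of the endodermis, 24 of 45 rose and 5 fell (24 and 6 adjusted over the list alone, median log2 change 0.57) (adjusted p = 4.33e-04, and 0.0144 with an estimated correlation). An omega-hydroxypalmitate O-feruloyl transferase (TRINITY_DN20660_c0_g3), which acts in suberin synthesis, rose from 23.5 ± 1.46 to 88.5 ± 1.84 TPM (log2 change 1.87). Photosynthesis genes moved with these groups: 28 of 50 rose and 1 fell (28 and 1 adjusted over the list alone, median log2 change 0.63) (adjusted p = 2.35e-05), a call that was lost on re-estimation (adjusted p = 0.0757 with an estimated correlation). A chlorophyll a-b binding protein (TRINITY_DN19345_c0_g2) rose from 329 ± 8.41 to 762 ± 20.4 TPM (log2 change 1.21).

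Phenylpropanoid and lignin enzymes, which make the precursors of lignin from phenylalanine, rose as a group: 69 of 108 members rose, 12 fell and 27 did not pass (69 and 14 adjusted over the list alone, median log2 change 0.53) (adjusted p = 7.44e-06, and 0.0115 with an estimated correlation). Caffeoyl-CoA O-methyltransferase (TRINITY_DN19579_c0_g2), which methylates a lignin precursor, rose from 45.2 ± 2.58 to 259 ± 14.6 TPM (log2 change 2.49). Laccase-3 (TRINITY_DN24921_c0_g2), of a family that oxidises lignin monomers, went the other way and fell from 165 ± 6.17 to 57.2 ± 1.17 TPM (log2 change -1.51). Of class III peroxidases 60 of 96 rose and 27 fell (60 and 27 adjusted over the list alone, median log2 change 0.93). The call did not hold (adjusted p = 0.0563 with an estimated correlation). Peroxidase 49 (TRINITY_DN20846_c0_g2) rose from 30.2 ± 0.68 to 160 ± 1.56 TPM (log2 change 2.36). In the flavonoid list 29 of 58 rose and 12 fell (29 and 13 adjusted over the list alone, median log2 change 0.27) (adjusted p = 0.288 with an estimated correlation). Dihydroflavonol 4-reductase (TRINITY_DN19609_c1_g5) rose from 11.8 ± 0.62 to 50.5 ± 1.53 TPM (log2 change 2.01). The flavonol synthase/flavanone 3-hydroxylase (TRINITY_DN21702_c0_g2) fell from 72.5 ± 4.06 to 2.40 ± 0.29 TPM (log2 change -4.44).

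Among hormone lists, auxin genes were called higher, with 27 rising and 11 falling of 53 (27 and 11 adjusted over the list alone, adjusted p = 0.0795 with an estimated correlation). Auxin-induced protein 5NG4 (TRINITY_DN16666_c0_g2) rose from 63.1 ± 1.27 to 143 ± 3.95 TPM (log2 change 1.17). Auxin transporter-like protein 1 (TRINITY_DN20505_c0_g3) fell from 66.8 ± 1.51 to 14.0 ± 1.25 TPM (log2 change -2.18). On the gibberellin list 10 of 16 rose and 4 fell (10 and 4 adjusted over the list alone, median log2 change 1.25) (adjusted p = 0.0831 with an estimated correlation), with Gibberellin-regulated protein 10 (TRINITY_DN19771_c0_g2) rising from 42.9 ± 2.20 to 242 ± 11.8 TPM (log2 change 2.47). Transcription factors of the WRKY family, many of which act in defence, were called lower: 6 of 40 rose and 17 fell (7 and 18 adjusted over the list alone, median log2 change -0.16) (adjusted p = 0.00866, and 0.0347 with an estimated correlation). Histones were called higher, with 43 rising and 11 falling of 82 (43 and 11 adjusted over the list alone, adjusted p = 0.183 with an estimated correlation). The largest rises included Ethylene-responsive transcription factor ERF016 (TRINITY_DN17680_c0_g1) (log2 change 4.58, 32.3 ± 3.52 against 0.40 ± 0.27 TPM), Heavy metal-associated isoprenylated plant protein 23 (TRINITY_DN15855_c0_g1) (log2 change 4.52, 72.2 ± 9.18 against 2.18 ± 0.39 TPM), Early nodulin-93 (TRINITY_DN22907_c0_g2) (log2 change 4.41, 23.7 ± 2.13 against 0.18 ± 0.31 TPM) and LTI6B (TRINITY_DN20568_c0_g3) (log2 change 4.79, 43.0 ± 1.55 against 0.60 ± 0.13 TPM). A polygalacturonase (TRINITY_DN22259_c0_g3), which cuts pectin, fell from 17.7 ± 2.74 to 0.35 ± 0.36 TPM (log2 change -3.82).

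The test called 12796 genes between dwarf and water roots, 7997 higher and 4799 lower, with 3064 and 1411 of them at 2-fold or more. Among conifer-matched contigs 939 were 2-fold higher and 246 lower. The ABC and MATE list was called higher, with 58 rising and 16 falling of 132 (59 and 16 adjusted over the list alone, adjusted p = 0.24 with an estimated correlation). Restricting it to conifer-matched contigs gave the other direction with no call (adjusted p = 0.847).

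Roots of seedlings whose growth had stopped were then compared with water roots. Among the comparisons with water, these held the largest fall of a named gene. Basic endochitinase CHB4 (TRINITY_DN23729_c0_g3), which cuts the chitin of fungal walls, fell from 454 ± 50.4 to 0.46 ± 0.40 TPM (log2 change -8.32). GDSL esterase/lipase At1g28670 (TRINITY_DN22113_c0_g4) rose from 0.75 ± 0.43 to 145 ± 6.86 TPM (log2 change 6.42). Fasciclin-like arabinogalactan protein 7 (TRINITY_DN19318_c0_g1) rose from 1.93 ± 1.00 to 174 ± 3.83 TPM (log2 change 5.96). A late embryogenesis abundant protein (TRINITY_DN24333_c0_g1), of a family that protects cells from drying, rose from 13.4 ± 0.51 to 497 ± 10.6 TPM (log2 change 5.12). Cationic peroxidase 2 (TRINITY_DN21321_c0_g1) fell from 336 ± 7.54 to 8.31 ± 3.34 TPM (log2 change -5.24). Alpha carbonic anhydrase 2 (TRINITY_DN23427_c0_g2) fell from 95.1 ± 5.99 to 2.88 ± 4.17 TPM (log2 change -5.17).

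The wall, xylem, cell division and water channel groups that were higher in dwarf roots were higher here too. Of cellulose synthases and structural wall proteins, 35 of 46 members rose, 2 fell and 9 did not pass (35 and 3 adjusted over the list alone, median log2 change 1.54) (adjusted p = 6.06e-12, and 0.00833 with an estimated correlation), with Fasciclin-like arabinogalactan protein 8 (TRINITY_DN17420_c0_g1) rising from 32.6 ± 1.70 to 302 ± 3.90 TPM (log2 change 3.17). On the xylem list 10 of 11 rose and 0 fell (10 and 0 adjusted over the list alone, median log2 change 2.60) (adjusted p = 1.68e-06, and 0.0102 with an estimated correlation). The annotation term xylem development, tested over conifer-matched contigs after the lists were seen, went the other way, with 4 of 22 rising and 13 falling. Among cell division genes 58 of 88 rose and 11 fell (58 and 11 adjusted over the list alone, median log2 change 0.89) (adjusted p = 1.13e-06, and 0.0494 with an estimated correlation). Over the 31 conifer-matched members the cell division call was lost (adjusted p = 0.0512). Among aquaporins 17 of 19 rose and 1 fell (17 and 1 adjusted over the list alone, median log2 change 1.47) (adjusted p = 7.04e-08, and 0.0144 with an estimated correlation). In the casparian strip and suberin list 30 of 45 rose and 7 fell (30 and 7 adjusted over the list alone, median log2 change 0.84) (adjusted p = 9.33e-05, and 0.0115 with an estimated correlation). The vacuolar aquaporin TIP1-1 (TRINITY_DN22221_c0_g1) rose from 462 ± 3.50 to 2523 ± 78.9 TPM (log2 change 2.45). Wall loosening genes were called higher, with 82 rising and 39 falling of 143 (83 and 39 adjusted over the list alone, adjusted p = 0.0531 with an estimated correlation). Xyloglucan endotransglucosylase/hydrolase protein 9 (TRINITY_DN22166_c0_g1) rose from 136 ± 2.53 to 638 ± 10.4 TPM (log2 change 2.23). Expansin-like B1 (TRINITY_DN23563_c1_g2) fell from 61.1 ± 0.80 to 2.70 ± 0.24 TPM (log2 change -4.07).

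Phenylpropanoid and lignin enzymes were higher: 67 of 108 members rose, 19 fell and 22 did not pass (68 and 19 adjusted over the list alone, median log2 change 0.81) (adjusted p = 3.02e-06, and 0.011 with an estimated correlation). Caffeoyl-CoA O-methyltransferase (TRINITY_DN19579_c0_g2) rose from 45.2 ± 2.58 to 581 ± 7.92 TPM (log2 change 3.66). Caffeic acid 3-O-methyltransferase (TRINITY_DN21256_c0_g1) rose from 135 ± 3.73 to 479 ± 12.7 TPM (log2 change 1.82). Of the flavonoid enzymes 32 of 58 rose and 16 fell (34 and 16 adjusted over the list alone, median log2 change 0.43) (adjusted p = 0.268 with an estimated correlation). Flavonoid 3'-monooxygenase (TRINITY_DN23273_c0_g2) rose from 7.71 ± 0.38 to 127 ± 1.36 TPM (log2 change 3.88). Terpenoid enzymes, which make isoprenoids and resin, were higher: 20 of 28 members rose, 3 fell and 5 did not pass (20 and 3 adjusted over the list alone, median log2 change 0.89) (adjusted p = 9.33e-05, and 0.0303 with an estimated correlation). The enzyme 1-deoxy-D-xylulose 5-phosphate reductoisomerase (TRINITY_DN22154_c0_g3), at an early step of the plastid isoprenoid pathway, rose from 13.2 ± 0.46 to 54.4 ± 0.94 TPM (log2 change 1.97). The (-)-alpha-pinene synthase (TRINITY_DN24434_c1_g2) rose from 149 ± 6.90 to 435 ± 19.0 TPM (log2 change 1.54). Class III peroxidases went both ways, with 58 rising and 32 falling of 96 (59 and 33 adjusted over the list alone, median log2 change 1.38). The list was called higher, but the call did not hold (adjusted p = 0.0604 with an estimated correlation). Peroxidase 27 (TRINITY_DN24138_c1_g5) rose from 0.53 ± 0.06 to 59.0 ± 2.47 TPM (log2 change 5.30). Peroxidase 49 (TRINITY_DN24267_c0_g1) rose from 45.1 ± 2.70 to 695 ± 12.8 TPM (log2 change 3.92).

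Defence-related proteins were divided. Of pathogenesis-related proteins 71 of 128 rose and 43 fell (71 and 45 adjusted over the list alone, median log2 change 0.46). The list was called higher, but the call held neither on re-estimation (adjusted p = 0.166 with an estimated correlation) nor over conifer-matched contigs, where its direction was lower (adjusted p = 0.95). Defensin-2 (TRINITY_DN14947_c0_g1), a small antimicrobial protein, rose from 22.3 ± 0.93 to 505 ± 20.7 TPM (log2 change 4.44). Pathogenesis-related protein PR-1 (TRINITY_DN20102_c0_g1) rose from 0.50 ± 0.05 to 62.4 ± 1.62 TPM (log2 change 5.40). PR-4B (TRINITY_DN16883_c0_g1) fell from 2434 ± 25.3 to 470 ± 13.5 TPM (log2 change -2.37). WRKY factors were lower: 6 of 40 rose and 23 fell (6 and 23 adjusted over the list alone, median log2 change -0.41) (adjusted p = 0.00117, and 0.0212 with an estimated correlation), with WRKY transcription factor 7 (TRINITY_DN14898_c0_g1) falling from 88.8 ± 1.20 to 34.6 ± 1.91 TPM (log2 change -1.34). NAC factors were called lower, with 7 rising and 21 falling of 29 (7 and 21 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation). NAC transcription factor ONAC010 (TRINITY_DN17931_c2_g2) fell from 58.6 ± 1.35 to 18.7 ± 0.87 TPM (log2 change -1.60).

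Mineral nutrient transporters were called higher, with 52 rising and 25 falling of 102 (53 and 25 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation). Contigs named NRT1/PTR family 7.3, of a family of nitrate and peptide transporters, went both ways, as TRINITY_DN24070_c0_g1 rose from 54.7 ± 4.27 to 230 ± 2.88 TPM (log2 change 2.06) and TRINITY_DN21788_c0_g2 fell from 50.2 ± 4.76 to 1.39 ± 0.12 TPM (log2 change -4.42). Unlike in the dwarf roots, photosynthesis genes were called lower, with 9 rising and 26 falling of 50 (9 and 26 adjusted over the list alone, median log2 change -0.31, adjusted p = 0.223 with an estimated correlation). The chlorophyll a-b binding protein of type I (TRINITY_DN23703_c0_g1) fell from 3172 ± 18.6 to 1314 ± 21.3 TPM (log2 change -1.27). In all 16819 genes were called between suppressed and water roots, 8306 higher and 8513 lower, of which 3637 and 4123 differed at least 2-fold. Among conifer-matched contigs the balance was the other way, with 1552 2-fold higher and 1021 lower.

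**Figure D2:**
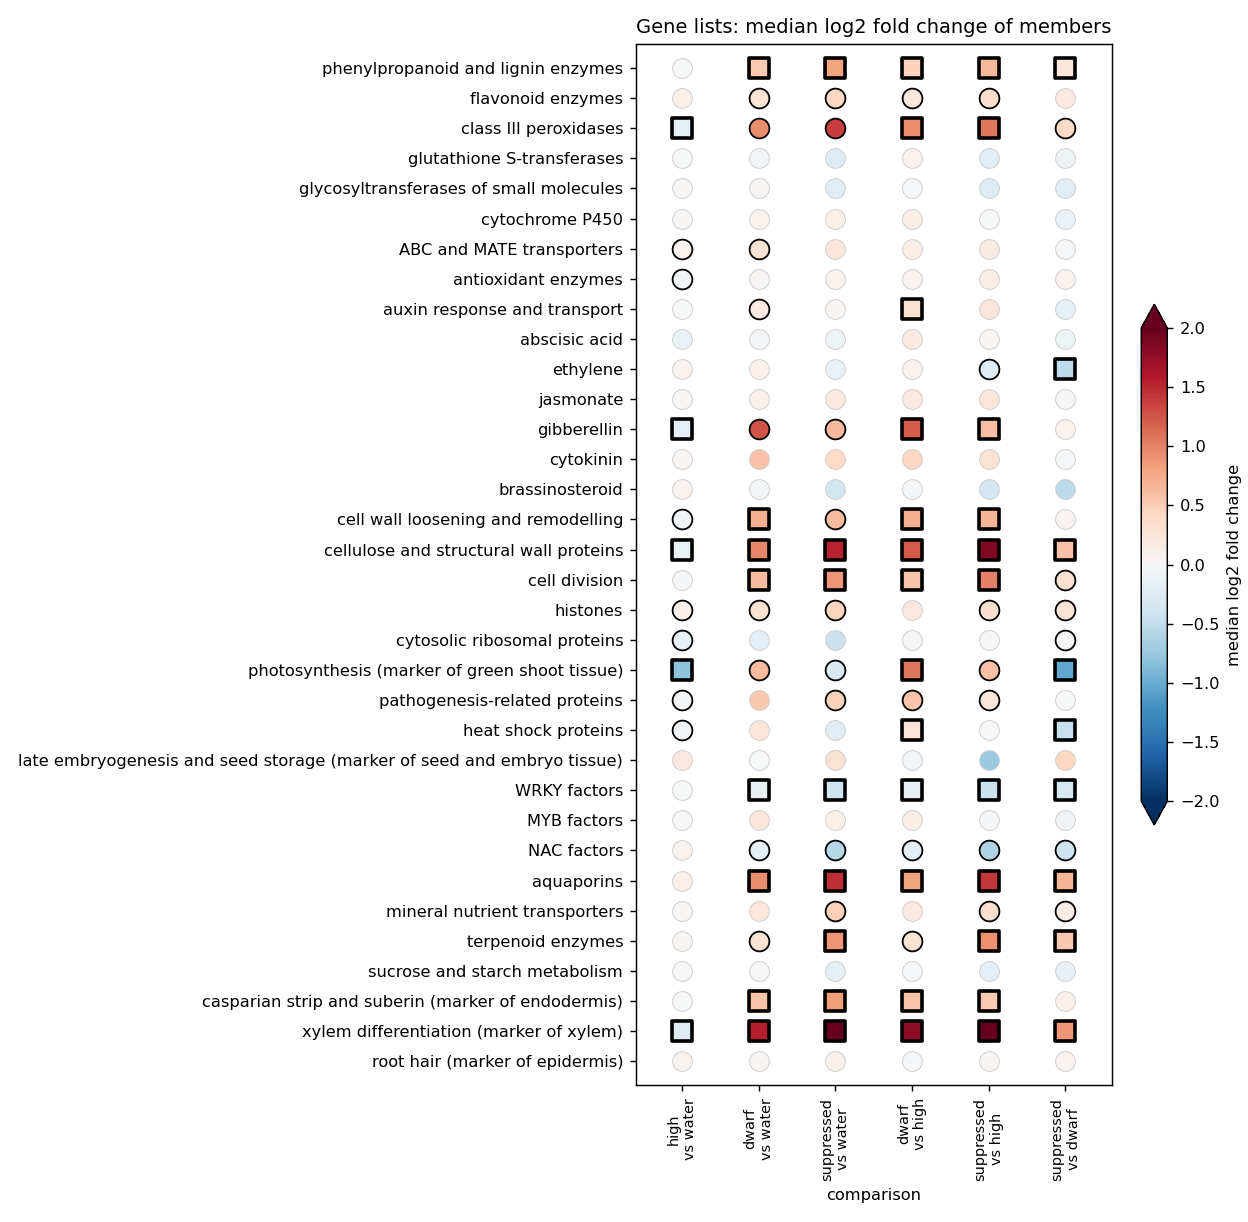
Median log2 fold change (colour, from -2.0 to 2.0) of the members of each of 34 gene lists (vertical axis) in the 6 pairwise comparisons (horizontal axis). Black outlines mark lists called by camera at an adjusted p under 0.05, squares those also called with an estimated correlation, and xylem, cellulose and aquaporin lists were higher in dwarf and suppressed roots than in water and high roots.

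Averaged over the 3 growth classes, DHAP roots differed from water roots in 14036 genes, 8183 higher and 5853 lower, of which 2541 and 1425 differed at least 2-fold. Genes higher in each of the 3 classes than in water numbered 1039, and 274 would be shared by independent lists of the same sizes. Genes lower in each numbered 1009, against 141.1 for independent lists. In simulated data where no group was changed, controls included, the number was 0 both ways. With no changed genes the adjustment leaves few calls that could overlap, so this 0 does not measure how far shared controls raise the overlap. Of the 394 genes at least 2-fold lower in each class, 91 had animal best hits and 53 conifer best hits. The fold changes against water had a Pearson's r across genes of 0.486 between high and dwarf, 0.182 between high and suppressed, and 0.677 between dwarf and suppressed, where simulated unchanged groups gave 0.5 to 0.504 from the shared controls alone. Their covariances were 0.339, 0.155 and 0.757, above the 0.0676 to 0.0683 that shared controls gave. The simulation took each gene's spread from all 4 groups together, and the 3 control libraries were not split between the comparisons. If the water samples varied more than that spread, part of the excess may still come from the shared controls.

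Within the treatment, dwarf roots were compared with high roots to ask what set short apart from tall seedlings. Peroxidases and photosynthesis genes were among the largest differences. Peroxidase 39 (TRINITY_DN24627_c0_g1) was higher in dwarf roots (log2 change 4.54, 670 ± 52.7 against 29.2 ± 12.0 TPM), as was Peroxidase 1 (TRINITY_DN18262_c0_g4) (log2 change 4.67, 74.2 ± 10.5 against 2.07 ± 1.03 TPM). Over the class III peroxidases 60 of 96 rose and 19 fell (62 and 21 adjusted over the list alone, median log2 change 0.93) (adjusted p = 3.47e-07, and 0.0144 with an estimated correlation). The small chain of ribulose bisphosphate carboxylase (TRINITY_DN17596_c0_g1) was higher (log2 change 4.33, 399 ± 21.6 against 18.9 ± 1.10 TPM). Of the photosynthesis genes 31 of 50 rose and 0 fell (31 and 0 adjusted over the list alone, median log2 change 1.08) (adjusted p = 8.21e-13, and 0.0144 with an estimated correlation). Endochitinase A (TRINITY_DN24742_c2_g5) was higher (log2 change 4.29, 215 ± 18.1 against 10.1 ± 1.81 TPM) and so was PRE6 (TRINITY_DN16104_c0_g2), a helix-loop-helix factor (log2 change 4.04, 19.7 ± 1.49 against 0.28 ± 0.27 TPM).

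The wall, xylem and division lists were again higher. Of cellulose synthases and structural wall proteins, 37 of 46 members rose, 2 fell and 7 did not pass (38 and 2 adjusted over the list alone, median log2 change 1.23) (adjusted p = 7.94e-14, and 0.00833 with an estimated correlation). All 11 genes of the xylem list, which overlaps the list before, were higher, with a median of 1.78 (adjusted p = 2.51e-08, and 0.00833 with an estimated correlation). Among wall loosening genes 94 of 143 rose and 21 fell (95 and 26 adjusted over the list alone, median log2 change 0.72) (adjusted p = 2.51e-08, and 0.0115 with an estimated correlation). Among cell division genes 58 of 88 rose and 4 fell (59 and 5 adjusted over the list alone, median log2 change 0.57) (adjusted p = 6.38e-09, and 0.0261 with an estimated correlation). Xyloglucan endotransglucosylase/hydrolase protein 31 (TRINITY_DN16380_c1_g3) was higher (log2 change 2.80, 60.6 ± 0.99 against 7.87 ± 0.16 TPM). Other lists called higher, with and without an estimated correlation, were phenylpropanoid and lignin enzymes (62 rose and 9 fell of 108), casparian strip and suberin (27 and 3 of 45), aquaporins (16 and 1 of 19), gibberellin (10 and 2 of 16), auxin (29 and 10 of 53) and heat shock proteins (67 and 18 of 136). Adjusted over the list alone, these counts were 65 and 10, 27 and 3, 16 and 2, 10 and 2, 29 and 10, and 68 and 18. The 18.1 kDa class I heat shock protein (TRINITY_DN18397_c2_g1), a small chaperone, was higher (log2 change 1.74, 1024 ± 27.1 against 306 ± 13.1 TPM). So was the auxin efflux carrier component 1a (TRINITY_DN20125_c0_g1) (log2 change 0.89, 106 ± 2.12 against 56.9 ± 0.84 TPM).

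Lower in dwarf than in high roots were the mannose-binding lectin (TRINITY_DN12880_c0_g1) (log2 change -3.96, 5.23 ± 0.49 against 95.9 ± 4.25 TPM), the sugar transporter SWEET3b (TRINITY_DN14572_c2_g1) (log2 change -3.38, 0.27 ± 0.16 against 12.2 ± 1.63 TPM) and Chitinase 3 (TRINITY_DN21209_c0_g2) (log2 change -1.61, 61.7 ± 1.52 against 191 ± 6.10 TPM). WRKY factors were called lower, with 4 rising and 17 falling of 40 (4 and 18 adjusted over the list alone, adjusted p = 0.00988, and 0.037 with an estimated correlation). In this comparison 12339 genes were called, 7101 higher and 5238 lower in dwarf roots, with 2442 and 1517 at 2-fold or more.

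Suppressed and high roots were the most different pair, with 17924 genes called, 8146 higher and 9778 lower in suppressed roots, of which 3518 and 5369 differed at least 2-fold. Among conifer-matched contigs more were 2-fold higher, 1493, than lower, 1129. The GDSL esterase/lipase At1g28670 (TRINITY_DN22113_c0_g4) was higher in suppressed roots (log2 change 6.92, 145 ± 6.86 against 0.22 ± 0.22 TPM). So were the late embryogenesis abundant protein (TRINITY_DN24333_c0_g1) (log2 change 6.59, 497 ± 10.6 against 4.18 ± 0.24 TPM), Peroxidase 39 (TRINITY_DN24627_c0_g1) (log2 change 6.37, 2375 ± 99.8 against 29.2 ± 12.0 TPM) and Casparian strip membrane protein 1 (TRINITY_DN22640_c0_g1), which organises the casparian strip (log2 change 4.83, 183 ± 1.57 against 5.54 ± 1.04 TPM). Lower were Basic endochitinase CHB4 (TRINITY_DN23729_c0_g3) (log2 change -8.32, 0.46 ± 0.40 against 454 ± 22.4 TPM), the lectin (TRINITY_DN12880_c0_g1) (log2 change -6.40, 0.16 ± 0.14 against 95.9 ± 4.25 TPM), Pathogenesis-related protein 1C (TRINITY_DN16377_c0_g2) (log2 change -4.08, 0.03 ± 0.03 against 16.5 ± 1.07 TPM) and Endoglucanase 17 (TRINITY_DN24180_c0_g2) (log2 change -3.82, 2.56 ± 0.18 against 49.1 ± 2.63 TPM).

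By list, cellulose and structural wall proteins were higher, as 38 of 46 members rose, 3 fell and 5 did not pass (38 and 4 adjusted over the list alone, median log2 change 1.85) (adjusted p = 5.70e-13, and 0.00833 with an estimated correlation). All 11 genes of the xylem list, which overlaps the list before, were higher, with a median of 2.82 (adjusted p = 2.87e-07, and 0.00833 with an estimated correlation). Of class III peroxidases 60 of 96 rose and 27 fell (61 and 28 adjusted over the list alone, median log2 change 1.06) (adjusted p = 2.89e-05, and 0.0246 with an estimated correlation). Of aquaporins 17 of 19 rose and 1 fell (17 and 1 adjusted over the list alone, median log2 change 1.42) (adjusted p = 1.81e-07, and 0.0163 with an estimated correlation). Of terpenoid enzymes 21 of 28 rose and 2 fell (21 and 2 adjusted over the list alone, median log2 change 0.91) (adjusted p = 1.43e-05, and 0.0234 with an estimated correlation). Cell division (1.01 median), phenylpropanoid and lignin enzymes (0.65), the casparian strip and suberin list (0.53), wall loosening (0.69) and gibberellin (0.60) were also called higher with both correlations. WRKY factors were called lower, with 5 rising and 26 falling of 40 (5 and 27 adjusted over the list alone, adjusted p = 0.00132, and 0.0212 with an estimated correlation). Photosynthesis genes were called higher, as 26 rose and 10 fell of 50 (26 and 10 adjusted over the list alone, adjusted p = 0.225 with an estimated correlation).

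The last pair, suppressed against dwarf roots, asked what set arrested from short seedlings. Photosynthesis genes were lower in suppressed roots: 4 of 50 members rose, 33 fell and 13 did not pass (4 and 33 adjusted over the list alone, median log2 change -1.04) (adjusted p = 3.73e-09, and 0.0247 with an estimated correlation). The chlorophyll a-b binding protein of type I (TRINITY_DN23703_c0_g1) was lower (log2 change -2.16, 1314 ± 21.3 against 5853 ± 99.2 TPM). Ethylene genes, mostly transcription factors of the ethylene-responsive family, were lower, as 11 of 78 members rose, 47 fell and 20 did not pass (12 and 47 adjusted over the list alone, median log2 change -0.52) (adjusted p = 1.94e-04, and 0.025 with an estimated correlation), with Ethylene-responsive transcription factor 2 (TRINITY_DN19211_c0_g2) lower (log2 change -1.19, 47.9 ± 1.09 against 111 ± 4.56 TPM). Among heat shock proteins 24 of 136 rose and 73 fell (25 and 74 adjusted over the list alone, median log2 change -0.45) (adjusted p = 2.50e-04, and 0.0328 with an estimated correlation). Chaperone protein ClpB1 (TRINITY_DN16571_c0_g1), which dissolves protein aggregates, was lower (log2 change -0.93, 69.0 ± 0.15 against 132 ± 2.15 TPM). WRKY factors were lower again, with 2 rising and 23 falling of 40 (2 and 23 adjusted over the list alone, adjusted p = 0.00188, and 0.023 with an estimated correlation).

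Higher in suppressed than in dwarf roots were terpenoid enzymes (19 of 28 rose and 4 fell (19 and 5 adjusted over the list alone, median log2 change 0.55), adjusted p = 2.97e-05, and 0.0247 with an estimated correlation), among them a levopimaradiene synthase (TRINITY_DN23598_c1_g1), an enzyme of resin acid synthesis (log2 change 3.38, 12.0 ± 2.47 against 0.24 ± 0.22 TPM). The (+)-alpha-pinene synthase (TRINITY_DN21054_c0_g4) was higher too (log2 change 1.94, 84.4 ± 3.89 against 21.3 ± 0.32 TPM). Cellulose and structural wall proteins (33 rose and 5 fell of 46, median 0.58), xylem (9 and 1 of 11, 0.88), aquaporins (14 and 2 of 19, 0.67) and phenylpropanoid and lignin enzymes (45 and 22 of 108, 0.22) were called higher with both correlations. Adjusted over the list alone, these counts were 33 and 5, 9 and 1, 14 and 2, and 46 and 23. Major allergen Pru ar 1 (TRINITY_DN16655_c0_g1), of a family of pathogenesis-related proteins, was higher (29.1 ± 2.08 against 0.43 ± 0.14 TPM), as was Dirigent protein 23 (TRINITY_DN21501_c0_g3), of a family that steers the coupling of phenolic radicals (log2 change 3.33, 31.1 ± 1.72 against 2.19 ± 0.16 TPM). Cytosolic ribosomal proteins were called higher although their median was 0 and their mean log2 change -0.11 (adjusted p = 0.376 with an estimated correlation). Of their 519 members, 300 had fungal or animal best hits. Without those contigs 103 rose and 24 fell. Called genes numbered 13976, 5994 higher and 7982 lower, with 1373 and 3005 at 2-fold or more. Over conifer-matched contigs alone 3228 were higher and 3166 lower.

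**Figure D3:**
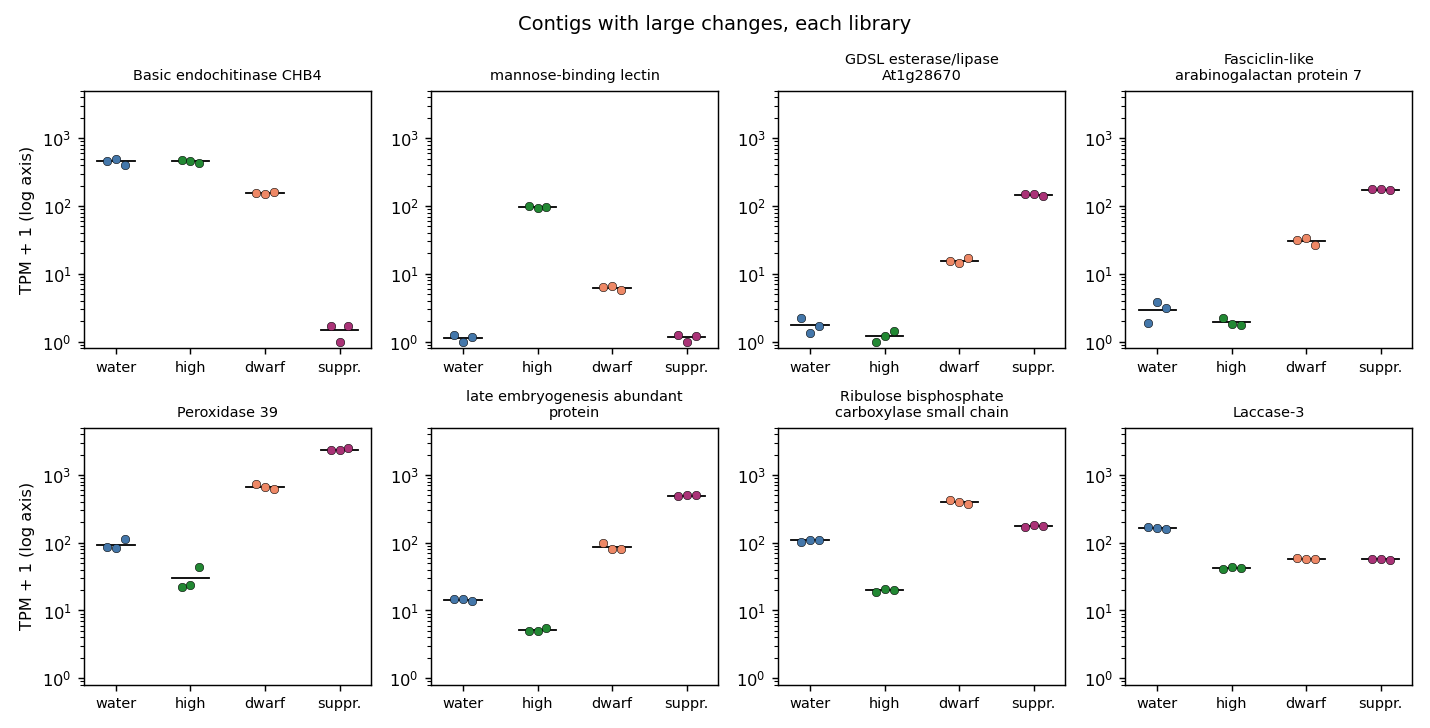
TPM + 1 on a log axis of 8 contigs chosen from the genes named in the text, in each of 12 libraries (points) of the 4 groups, with a line at each group's mean. Basic endochitinase CHB4 falls to 0.46 TPM in suppressed roots, the mannose-binding lectin reaches 95.9 TPM in high roots, and 4 contigs, the GDSL esterase/lipase, Fasciclin-like arabinogalactan protein 7, Peroxidase 39 and the late embryogenesis abundant protein, are lowest in high and highest in suppressed roots.

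Taking the 3 growth classes in the order high, dwarf, suppressed, 3589 genes rose in dwarf against high and again in suppressed against dwarf roots, where 1582.5 would do so if the calls were independent. Another 2845 fell both times, against 1554.4. Fewer genes than for independent calls rose and then fell, 1714 against 2107.3, or fell and then rose, 419 against 1167.3. Both comparisons use the dwarf libraries with opposite sign, so chance values of these libraries favour the last pair of patterns.

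Of the 34 lists, 11 were called in none of the 6 comparisons, and the smallest adjusted p among them was 0.119. They include families known for modifying foreign compounds. In suppressed against water roots, 13 of 45 glutathione S-transferases rose and 20 fell (median -0.26), 24 of 75 glycosyltransferases rose and 33 fell (-0.23), and 40 of 106 cytochrome P450 enzymes rose and 37 fell (0.12), and the counts adjusted over the list alone were 13 and 20, 24 and 33, and 40 and 38. Also not called were the abscisic acid, jasmonate, cytokinin, brassinosteroid, MYB, sucrose and starch, late embryogenesis and seed storage, and root hair lists. Their smallest adjusted p-values were 0.134, 0.160, 0.183, 0.193, 0.236, 0.199, 0.158 and 0.383, in that order. Over all 204 tests, 54 of 96 calls held with an estimated correlation, and the median, mean and test differed in sign in 1 call, that of the ribosomal list, and in 36 tests in all.

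Contigs whose best hits lay in other organisms differed between the groups as well. Fungal-like contigs summed to 5912 ± 35.5 TPM in water, 7139 ± 141 TPM in high, 6946 ± 139 TPM in dwarf and 3600 ± 35.7 TPM in suppressed roots (n = 3 each). In suppressed against dwarf roots, 3 of 631 such contigs were 2-fold higher and 333 were 2-fold lower. All animal-like contigs together made up 1.49 ± 0.149% of TPM in water, 1.18 ± 0.0494% in high, 1.20 ± 0.0348% in dwarf and 1.22 ± 0.0138% in suppressed roots. The 91 of them picked for being 2-fold lower in each DHAP group summed to 1482, 1671 and 591 TPM in the 3 water libraries, and to 165 ± 68.4 TPM in high, 145 ± 65.1 TPM in dwarf and 309 ± 48.1 TPM in suppressed roots. Ribosomal, histone and antioxidant lists hold contigs of these kinds, with 300 of 519, 16 of 82 and 17 of 99 members.

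**Figure D4:**
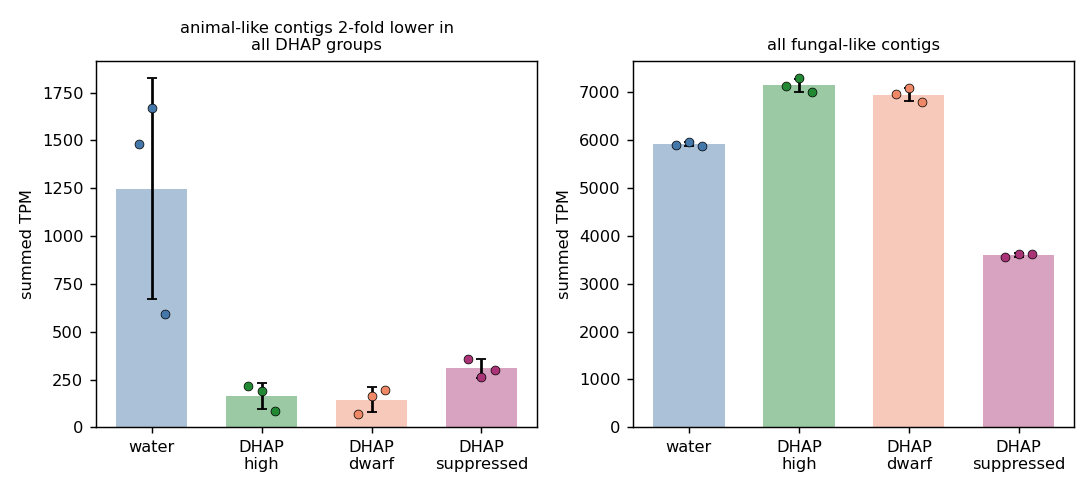
Summed TPM of the 91 animal-like contigs that were at least 2-fold lower in all DHAP groups (left) and of all fungal-like contigs (right), with bars at group means, error bars of 1 SD and points for the 3 libraries of each group. The animal-like sum is lower in water replicate 3, at 591 TPM, than in the other water libraries, and the fungal-like sum is lowest in suppressed roots, at 3600 TPM.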

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

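The tests of library scaling, shoot tissue and root tips, that of depth for the animal-like contigs, the lists over conifer-matched contigs and the count of all splits of 3 libraries against 9 were chosen only after the results were seen. The other counts of splits were chosen before. The prediction on animals on the roots was written before its test, but the contigs it was applied to were picked from these results.

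For 7 lists, the response was called against water in opposite directions in 2 growth classes, and a direct test between the classes with camera passed. With an estimated correlation, only the xylem and the cellulose and structural wall lists kept the calls against water in both directions. Calls were lost for class III peroxidases (adjusted p = 0.0563 in dwarf, 0.0604 in suppressed), gibberellin (0.0831 and 0.0777 in that order) and wall loosening (0.124 in high, 0.0531 in suppressed). They were also lost for photosynthesis (0.0757 in dwarf, 0.223 in suppressed) and pathogenesis-related proteins (0.0631 in high, 0.166 in suppressed). Direct tests also passed for other lists that were not called in opposite directions, as the comparisons above give. Genes of the xylem list had medians against water of 1.55 in dwarf and 2.60 in suppressed roots and -0.25 in high roots (direct tests against high, adjusted p = 2.51e-08 and 2.87e-07). The fasciclin-like arabinogalactan proteins among them are also on the cellulose and structural wall list, so the xylem and wall results are not separate evidence. Cellulose and structural wall proteins had 0.98 and 1.54 against -0.13 (adjusted p = 7.94e-14 and 5.7e-13), and wall loosening genes 0.73 and 0.63 against -0.08 (adjusted p = 2.51e-08 and 0.000679). Class III peroxidases had 0.93 and 1.38 against -0.16 (adjusted p = 3.47e-07 and 2.89e-05), and the gibberellin list 1.25 and 0.65 against -0.20 (adjusted p = 0.000937 and 0.00894). Photosynthesis genes had 0.63 in dwarf against -0.80 in high roots (adjusted p = 8.21e-13) and -0.31 in suppressed against 0.63 in dwarf roots (adjusted p = 3.73e-09). Pathogenesis-related proteins had 0.46 in suppressed and -0.03 in high roots (adjusted p = 0.015), the only one of these direct tests that did not pass with an estimated correlation (adjusted p = 0.102). Over conifer-matched contigs, chosen after seeing the data, the direct tests no longer passed for class III peroxidases in dwarf and suppressed roots (adjusted p = 0.0665 and 0.528), nor in suppressed roots for gibberellin (0.186), wall loosening (0.214) and pathogenesis-related proteins (0.901).

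Of 154 cell wall, xylem, cell division and aquaporin genes, 110 to 116 rose and 7 to 18 fell in dwarf and suppressed roots against water and high roots, and scaling of the libraries is argued against, since the smallest median was 0.753 and the scaling factors spanned 0.102 on the log2 scale. A larger share of root tips as the whole cause is argued against only as far as the casparian strip and suberin list marks mature endodermis. Its word patterns take in any CASP-like protein, so it is a rough marker. The list shares 0 genes with the others and had smallest medians of 0.569 in dwarf and 0.528 in suppressed roots, with lower quartiles above 0. In suppressed roots its 14 conifer-matched contigs had medians of 0.70 against water and 0.17 against high, without a call (adjusted p = 0.157 and 0.331). More shoot tissue as the whole cause is argued against for suppressed against water roots, where 11 of 13 photosynthesis contigs abundant in water were lower and 1 higher. Picking contigs by their level in water favours falls, but over the whole list 26 of 50 fell and 9 rose. The list median was -0.309, a call not held with an estimated correlation. Against high roots, 8 of the 13 were higher in suppressed roots and 5 lower, and the list was called higher without holding. Shoot tissue is thus not decided for that comparison. It also stays open for dwarf roots, where 10 of the 13 were higher than in water (list median 0.629) and all but 1 higher than in high roots. A hypothesis of biological differences that came with DHAP or with the growth class stays open too, because the classes were not assigned.

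Photosynthesis genes were lower in high roots than in water roots, and 28 of 50 were higher in dwarf roots, a call not held with an estimated correlation (adjusted p = 0.0757). For the rise in dwarf roots, scaling is argued against by the median of 0.629 beside the range of 0.102. Of the 13 contigs at 100 TPM or more in water roots, 10 were higher in dwarf roots and 3 were not (Photosystem I reaction center subunit N, Photosystem I subunit O and Oxygen-evolving enhancer protein 3-2, log2 changes 0.07, -0.42 and -0.01, named after their values were seen), so that shoot tissue and a change within root cells cannot be told apart without levels measured in shoots. For the fall in high roots, 0 of the 13 failed to fall, so that less shoot tissue among the high roots stays open, as does a change within root cells. The 13 were picked by their level in water, which favours falls. Their falls were unequal, from a log2 change of -0.15 (Photosystem I reaction center subunit IV A) to -2.45 (small chain of ribulose bisphosphate carboxylase).

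The 91 animal-like contigs were at least 2-fold lower in each DHAP group than in water roots. A lower depth of the DHAP libraries is argued against: of conifer-matched contigs at 5 to 60 TPM in water, 0.016%, 0.032% and 0.224% were under 0.5 TPM in high, dwarf and suppressed roots, against 4.13%, 6.60% and 3.99% of animal-like contigs at that level. The median log2 ratio of water replicate 3 to the other water libraries was -1.42 over the 91 contigs (quartiles -1.68 and -1.04), against 0.03 for the conifer-matched contigs of like level and -0.05 (quartiles -1.15 and 0.07) for all 727 animal-like contigs of that level. Such shared variation of the 91 contigs between libraries of 1 group may come from small animals living on the roots, which stays open. Whether DHAP affects such animals was not tested.

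Other splits of the libraries bear on the counts of genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits of only the 2 groups compared, the real split called 4506 genes for high against water, 11465 for dwarf against water, 15714 for suppressed against water, 12054 for dwarf against high, 17541 for suppressed against high and 13112 for suppressed against dwarf, and the highest of the other splits called 2, 0, 0, 0, 0 and 1. In each case 1 of the 10 splits, the real one, gave as many.

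For the 3 water libraries against the 9 DHAP libraries in a fit of 2 groups, 1 of 100 splits drawn, the real one, gave as many genes as its 1069, and the highest of the others, which set the dwarf libraries apart, gave 953. This fit counts the differences among the DHAP groups as spread, so its count lies below the 14036 of the fit with 4 groups. Over all 220 splits, 2 gave as many, the real one and that of the suppressed libraries, with 13784 genes, and the 216 splits that mixed groups gave at most 79. This points to a structure of the samples by group. Splits that mix groups count the differences between groups as spread and so can call few genes. They therefore cannot exclude chance as the source of the count, such as chance differences between pools. Setting apart the high or dwarf libraries also gave 586 or 953 genes, so the rank does not single out water against DHAP.

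For gene lists, 1 of 100 regroupings of the 12 libraries, the real one, gave as many calls as its 96. The highest of the others gave 86 and their median was 49. Regroupings that mix the groups also count their differences as spread, so the rank shows only that the total goes with the group labels. It does not bear on single list calls at the preset correlation. If the libraries of a group came from a single pool, chance differences between pools are not excluded.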

How the results depend on the processing

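The restrictions to contigs by best hit, and the scaling of the libraries for gene lists, were chosen only after the data were seen, and the other alternatives before.

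Requiring a 2-fold change left 1957 of the genes called between high and water roots, 4475 for dwarf against water, 7760 for suppressed against water, 3959 for dwarf against high, 8887 for suppressed against high, 4378 for suppressed against dwarf and 3966 for the mean of DHAP against water, which is by construction a subset. Testing only the 9596 conifer-matched contigs gave 2594, 5862, 7386, 5788, 7409, 6394 and 6273 in the same order, where fewer genes were tested. Among these the share of called genes that were higher was 56.8% rather than 49.4% for suppressed against water, 55.4% rather than 45.4% for suppressed against high and 50.5% rather than 42.9% for suppressed against dwarf. With the replicate number as a block the counts were 5155, 12511, 16605, 12081, 17779, 13737 and 13743. Leaving out each library in turn gave 4249 to 5003, 11306 to 11908, 15622 to 16206, 10679 to 11126, 16655 to 16958, 12743 to 12982 and 12062 to 13860. Median-of-ratios scaling, no trend, no filter, a filter of 5 TPM, a pseudocount of 0.1 and a fit of only the libraries compared each kept the counts within 1.5 times. The last was not run for the mean of DHAP, which already uses all libraries. Median-of-ratios scaling turned the majority for high against water, from 54.4% to 46.0% higher.

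Of the 96 list calls, 54 held with an estimated correlation, which allows for more correlation between members. With fry, which tests members without reference to other genes, 184 of 204 tests were called, among them 95 of the 96. The block gave 95 calls and leaving out a library 91 to 96, without a change of direction. The calls lost on leaving out 1 or more libraries were ABC and MATE transporters, antioxidant enzymes and histones in high against water, auxin, flavonoid, histone and terpenoid lists in dwarf against water, pathogenesis-related proteins in suppressed against water, flavonoid enzymes in dwarf against high and ethylene in suppressed against high. Scaling gave 94 calls (92 of the 96), leaving out fungal-like and animal-like contigs 99 (94 of the 96) and conifer-matched contigs alone 65 of 192 tests (57 of the 96), where fewer members were tested. Among the calls lost there were class III peroxidases in all comparisons but high against water, and the casparian strip, gibberellin and wall loosening lists in suppressed against water and against high. Cell division was lost in suppressed against water (adjusted p = 0.0512), and WRKY factors in dwarf against water (0.119) and against high (0.197). So were auxin in dwarf against high (0.186) and gibberellin in high against water (0.157).

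Some lists changed direction. With fry, lists that camera had leaning lower in dwarf against water, with no call, were higher: antioxidant enzymes (adjusted p = 0.000192), abscisic acid (5.76e-05), ethylene (0.00656), late embryogenesis and seed storage (0.00194), and sucrose and starch (0.0205). The cause was not tested. Ribosomal proteins in suppressed against water leaned lower in the main test without a call (adjusted p = 0.951). They turned higher without fungal-like and animal-like contigs (adjusted p = 0.00073) and among conifer-matched contigs (1.33e-09). The lower lean thus came with the contigs of fungal or animal best hit, whose organism of origin was not tested. Among conifer-matched contigs, ABC and MATE transporters in dwarf against water (adjusted p = 0.847) and pathogenesis-related proteins in suppressed against water (0.95) leaned lower without a call. The cause was not tested.

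All 274 results for named genes kept their direction and call under each alternative that tested them, except that 39 did not reach a 2-fold change and 1 was removed by the filter of 5 TPM. These genes were picked from the same libraries for large changes or small p-values, so this outcome was largely set in advance. Low values of short contigs rest on a few reads, so a change in a contig near 1 TPM is limited by depth.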

Other observations

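The tests of annotation terms reported here were all chosen only after the results of the lists were seen.

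Terms from the annotation were tested with camera over conifer-matched contigs, 352 terms in 6 comparisons, and 501 of the 2112 tests were called, of which 0 held with an estimated correlation. In suppressed against water roots, 25 of 28 contigs of mitochondrial respiratory chain complex I rose and 0 fell (median log2 change 1.02, adjusted p = 2.66e-06, 0.17 with an estimated correlation). Of 77 contigs of the cytosolic large ribosomal subunit 60 rose and 8 fell, of 20 in the proteasome complex 18 rose and 0 fell, and of 88 in protein ubiquitination 22 rose and 55 fell. Of 22 contigs of xylem development 4 rose and 13 fell (median -0.54, 0.173 with an estimated correlation). Against dwarf roots 4 of these rose and 17 fell (0.161 with an estimated correlation). By contrast, of 16 contigs of plant-type secondary cell wall biogenesis, 14 rose and 1 fell against water roots. Complex I was also higher in suppressed than in dwarf roots, with 28 of 28 higher (median 0.66, 0.132 with an estimated correlation). In dwarf against water roots 2 of 15 contigs of asparagine biosynthesis rose and 10 fell (median -0.69, 0.188 with an estimated correlation). In high against water roots, 26 of 37 contigs of the plastoglobule, a lipid body of plastids, fell and 1 rose (median -0.54, 0.0827 with an estimated correlation).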
